A study of Taeniopygia guttata with 23 samples.

How the data were processed

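Chromatin immunoprecipitation libraries of H3K4me3, H3K27me3, H3K9me3 and Pol II from dissected auditory forebrain of male zebra finches were made from formaldehyde-fixed, sonicated tissue and sequenced on an Illumina instrument, per the labels' protocols. There were 2 Tutored, 2 Isolate and 1 P32 library per mark, plus 3 input samples that were not used here. Groups and replicate numbers were taken from the sample labels. The labels give day 67 for Tutored and Isolate birds, while the series' design text gives day 65. How many birds went into a library, and whether replicates were separate birds, is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

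The submitters' processing notes name BWA 0.6.1, SICER 1.1 and MACS, with no role or order. The genome build is not given in the sources used here, so coordinates are those of the deposited islands, 1-based, on a build without a name. The names of the deposited files give a window of 200 bp, a gap of 200 bp for H3K4me3 and 600 bp for the other marks, and a false discovery rate of 1E-5, which are settings of the island caller SICER. Islands were called in each library separately. The deposited values are counts of ChIP reads per island, given as whole numbers. A tag in the deposited names may mean that reads were brought to a common number before islands were called, which no label explains. In the 6 replicate 2 lists of H3K27me3, H3K9me3 and Pol II, the authors also deposited the count of input reads, a p-value, a fold over input and an FDR q-value per island. These are the authors' own values and were used only to learn relative depth. The count ratio of ChIP to input, divided by the deposited fold, was 1.72 for H3K27me3, 0.697 for H3K9me3 and 1.48 for Pol II, with the same value in Tutored and Isolate to 6 decimals. The replicate 2 lists of these marks thus rest on equal numbers of reads, which may have been set by the authors, and the depth of sequencing itself stays unknown. The total depth of the libraries is not given in the sources used here. Reads outside islands were not in the lists, which means that an uncalled region has an unknown rather than a zero count.

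Islands of the libraries of a mark were merged into regions where they overlapped or touched, over the 4 P67 libraries or over all 5. A region counted as called in a library when an island overlapped it by at least 1 bp. Regions called in both libraries of a group and neither of the other were counted and set beside the other 2 ways of pairing the 4 libraries. The odds ratio of same-way calls compared regions whose calls differed between the groups in both replicates, with a large-sample 95% interval and, for strata, a Mantel-Haenszel estimate with its Robins-Breslow-Greenland interval. The base-pair Jaccard index was computed for all pairs of libraries. Shares of 1 mark inside another were computed in 200 bp windows, and their expected value from the covered share of each chromosome. Counts scaled to library size (CPM) use as library size the reads in all islands of the library for the longest regions, and the reads in the tested regions for the kinds of H3K4me3 region. Chromosome lengths were taken as the highest island end in any list. The 35 chromosomes were classed as large autosomes (at least 50 Mb, 6), Z, middle (8) and small (under 20 Mb, 20). Exact binomial intervals and other intervals on counts of regions cover counting error only.

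Reads per region were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, Benjamini-Hochberg adjusted p of 0.05) in R 4.3.3. Isolate was compared with Tutored over the 4 P67 libraries in regions called in all 4, and P32 with the mean of the P67 groups in regions called in all 5. Standard errors of log2 folds were derived from the fold and the F statistic. DESeq2 1.42.0 was an alternative tool. Other alternatives were RLE size factors, a mean of at least 50 reads, regions called in at least 2 libraries with uncalled libraries set to 0 reads, the covered length as an offset, a replicate block, each P67 library left out, islands covering at least 50% of a region, islands within 1000 bp merged, and the same number of islands per library, ranked by reads per kb. For H3K4me3 the replicate 1 groups were also exchanged. The groups, tests, alternatives and the rule for named regions were fixed before the data were examined, and the few chosen later are said to be so.

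The replicate numbers were taken to pair the samples, since the inputs are labelled as pools for replicate 1 and replicate 2. For Pol II replicate 1 the deposited names carry another replicate number than the titles, and the titles were followed. Deviations of same-numbered libraries from their group means correlated across regions at r = 0.788 for H3K4me3, 0.613 for H3K27me3, 0.426 for H3K9me3 and 0.625 for Pol II. The count tests were tested on simulated data with 100 regions changed at each of 2-fold and 4-fold. All simulated regions of a mark had 1 common spread, and the data for the test without a block had no replicate effect. Regions named in the text follow the rule set for lists without an annotation. The rule takes 2 per direction with most reads per kb in the weaker library among regions called in 1 P67 group alone, and 2 per direction with the largest log2 fold among regions past the adjusted p of 0.05. No annotation of the build of the islands was used here, so no region is assigned to a gene, exon or intron, and the gene lists that had been fixed in advance were not analysed here. Interval operations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, scipy 1.17.1 gave exact intervals and figures were drawn with matplotlib 3.10.9.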

Results

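Chromatin of the auditory forebrain, the brain region in which songbirds process heard song, was profiled in young male zebra finches (Taeniopygia guttata) by chromatin immunoprecipitation and sequencing. Juvenile males of this species learn their song from an adult male, and the series concerns a longer period of learning in birds reared without one. Tutored males lived with an adult male and an adult female from day 21 after hatching, Isolate males lived with adult females alone from the same day, and both were taken on day 67. The third group, P32, was taken on day 32 from the home aviary. The antibodies recognised H3K4me3, a histone mark of promoters, H3K27me3, the mark left by Polycomb repressors, H3K9me3, a mark of heterochromatin, and RNA polymerase II (Pol II), the enzyme that transcribes genes. Each mark had 2 Tutored, 2 Isolate and 1 P32 library, 20 in all, and the day 67 groups are called P67 together.

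Each library was represented by its list of enriched intervals (islands) with the number of reads in each. Reads inside islands ranged from 4286003 to 11303863 for H3K4me3, from 5671633 to 8412117 for H3K27me3, from 1551076 to 2133615 for H3K9me3 and from 1579718 to 3780427 for Pol II. The number of islands ranged from 17061 to 19502 for H3K4me3, 21621 to 31185 for H3K27me3, 19002 to 24470 for H3K9me3 and 8589 to 19656 for Pol II. Replicate 1 and replicate 2 differed in a way that both P67 groups shared. In H3K4me3, islands of replicate 1 held 87.5 (Tutored) and 90.2 (Isolate) reads per kb, and those of replicate 2 held 279 in both groups. The P32 library stood at 148 reads per kb.

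The 4 marks differed in region length, and some pairs of marks overlapped often and others seldom. For the pairs given here this was broadly alike in the P67 groups. Among merged regions called in all 5 libraries, which favours long ones, the median was 3.2 kb for H3K4me3 (13513 regions). It was 8.2 kb for H3K27me3, 7.6 kb for H3K9me3 and 10.6 kb for Pol II. Median island lengths of single libraries lay closer, at 1600 to 2200 bp, 2400 to 4600 bp, 1800 to 3600 bp and 2400 to 3600 bp in that order. Islands were called with a gap of 200 bp for H3K4me3 and 600 bp for the others, so part of the difference may come from this setting. Pol II lay over 35.4% ± 22.9 of H3K4me3 windows in Tutored and 47.5% ± 14.7 in Isolate (SD, n = 2 each), which is 4.11 ± 0.473 and 4.76 ± 0.0393 times the share that its cover of each chromosome gives. H3K9me3 windows lay inside H3K27me3 islands in 54.6% ± 1.47 of cases in Tutored and 52.4% ± 1.08 in Isolate, 4.17 ± 0.589 and 4.11 ± 0.491 times the share from cover alone. H3K4me3 and H3K9me3 shared few windows, with 3.57% ± 0.477 of H3K4me3 windows inside H3K9me3 islands in Tutored and 2.96% ± 0.356 in Isolate. Of the 14349 H3K4me3 regions called in all 4 P67 libraries, 2524 carried Pol II in all 4 and H3K27me3 in none. These had a median length of 4.6 kb and 20.9 H3K4me3 reads per kb after scaling to library size (CPM per kb). Another 846 carried H3K27me3 in all 4 libraries and Pol II in none, with a median of 2.2 kb and 7.88 CPM per kb. Both Pol II and H3K27me3 were present in all 4 libraries at 302 regions.

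The Z chromosome was the most H3K9me3-covered of the 7 chromosomes of at least 50 Mb in every library of that mark. Islands covered 13.6% ± 2.54 of Z in the P67 libraries (SD, n = 4), against 6.68% ± 1.37 of the large autosomes and 6.21% ± 0.530 of chromosomes under 20 Mb. The ratio of Z to the large autosomes was 2.05 ± 0.0570 in P67 and 2.503 in P32. Z stood at 0.986 ± 0.00904 times the large autosomes for H3K4me3, 1.01 ± 0.0536 for H3K27me3 and 1.07 ± 0.0264 for Pol II in P67. Chromosomes under 20 Mb were covered 2.56 ± 0.443 times as densely as large autosomes by H3K4me3, 2.24 ± 0.425 times by H3K27me3 and 4.06 ± 1.04 times by Pol II.

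**Figure D1:**
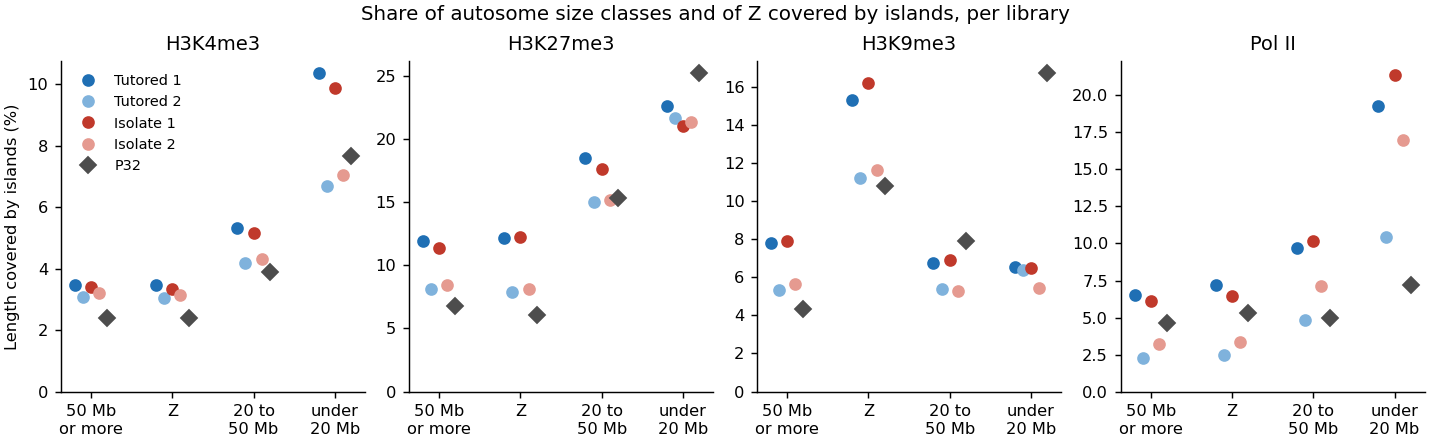
Share of the length (%) of autosomes of 50 Mb or more, of Z, of chromosomes from 20 to 50 Mb and of those under 20 Mb that islands covered, with 1 point per library and the P32 library as a diamond. H3K9me3 covered 13.6% of Z on average in the P67 libraries against 6.68% of large autosomes, and 16.7% of the smallest chromosomes in P32.

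Among regions chosen for being called in all 5 libraries, the longest of H3K27me3, on chromosome 14 at 8526201 to 8712400 (186 kb), was covered over 180 ± 5.23 kb in Tutored and 172 ± 4.38 kb in Isolate (SD, n = 2 each). The next, on chromosome 3 at 56583001 to 56754200, held 1157 ± 65.5 CPM in Tutored and 1157 ± 96.1 in Isolate. A 90.8 kb H3K9me3 region on chromosome 1 at 97169801 to 97260600 was covered over 83.1 ± 3.25 kb in Tutored, 84.1 ± 3.25 kb in Isolate and 77.4 kb in P32. The longest Pol II region, 254 kb on chromosome 3 at 22108601 to 22362800, was covered over 142 ± 145 kb in Tutored, 135 ± 150 kb in Isolate and 239 kb in P32, so its cover differed between replicates. It held 1425 ± 1014 CPM in P67 and 4543 in P32. These regions were picked for their length after their values had been seen.

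The first comparison, Isolate against Tutored at day 67, asks whether the missing adult male goes with another chromatin state. For H3K4me3 the groups had almost the same regions. Of 20267 merged regions, 94 were called in both Isolate libraries and neither Tutored library, and 58 in both Tutored libraries alone. By contrast, 568 were called in both replicate 1 libraries alone and 1385 in both replicate 2 libraries alone. The named Isolate-only regions lay on chromosome 1 at 4998401 to 4998600 (14 and 22 reads in replicates 1 and 2) and on chromosome 5 at 38712401 to 38712800 (24 and 54 reads). The named Tutored-only regions lay on chromosome 1A at 18090801 to 18091200 (19 and 37 reads) and at 53098601 to 53099000 (19 and 34 reads), the latter also called in P32. All 4 are at most 0.4 kb long and carried no other mark in any library. The region on chromosome 1 was barely called, since the fewest reads in any island were 13 in Isolate replicate 1 and 22 in Isolate replicate 2. Regions with H3K27me3 but no Pol II differed between Isolate and Tutored by a median log2 of -0.08 in replicate 1 and 0.01 in replicate 2, and those with Pol II but no H3K27me3 by -0.02 and 0.00. The replicate 1 files of H3K4me3 carry in their names the letter of the other group, and the labels were followed. With those libraries exchanged, the counts became 131 and 35, and the 4 named regions, chosen by the labels, then lie in mixed pairs by construction. With equal numbers of islands per library, 79 were Isolate-only and 98 Tutored-only, so which group had more depended on the number of islands.

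H3K27me3 was called in 285 regions in both Isolate libraries alone and in 521 in both Tutored libraries alone, of 30711. The pairs that mix the groups held 401 (Tutored 1 with Isolate 2) and 361 (Tutored 2 with Isolate 1). Isolate-only examples were chromosome 1 at 154601 to 155400 (46 and 55 reads) and chromosome 12 at 12159001 to 12159800 (39 and 100 reads), the latter also in P32. Tutored-only examples were chromosome 15 at 10029401 to 10030000 (30 and 39 reads) and chromosome 5 at 59231001 to 59231600 (39 and 40 reads). Of the H3K27me3 regions called in all 4 libraries, 15.0% overlapped H3K4me3 regions of all 4, and of the Isolate-only and Tutored-only regions 2.81% and 2.11% did. The latter were also shorter, with medians of 3.6 and 3.4 kb against 7.6 kb, and shorter regions overlap less often by length alone.

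H3K9me3 was called in 682 regions in both Isolate libraries alone and in 736 in both Tutored libraries alone, of 32033. The mixed pairs held 532 and 735. Isolate-only examples lay at 5601 to 6400 on chromosome 9 (25 and 64 reads) and 10381401 to 10381800 on chromosome 2 (21 and 23 reads). Tutored-only examples lay at 1201 to 1600 on chromosome 5 (27 and 32 reads) and 91422601 to 91423000 on chromosome 1 (20 and 17 reads). The latter was barely called, since the fewest reads in any island were 16 in Tutored replicate 1 and 13 in Tutored replicate 2. Among regions called in 1 group alone within each replicate, the odds of lying in Isolate in replicate 2 were 1.28 times as high where replicate 1 also had them in Isolate (95% interval 1.102 to 1.495). This interval included 1 when islands had to cover 50% of a region (0.993 to 1.31) and with equal numbers of islands per library (0.926 to 1.26). The same odds ratio was 1.19 (0.724 to 1.95) for H3K4me3 and 1.03 (0.838 to 1.26) for H3K27me3.

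Pol II had the most unequal counts of regions in 1 group alone. It was called in 735 regions in both Isolate libraries alone and in 100 in both Tutored libraries alone, of 23609. Both replicate 1 libraries alone held 3905 and both replicate 2 libraries alone 254. The mixed pairs held 317 (Tutored 1 with Isolate 2) and 87 (Tutored 2 with Isolate 1). In every split the pair without Tutored replicate 2 thus held more regions than the pair with it. Of regions that overlapped an H3K4me3 region of all 4 P67 libraries, 423 were Isolate-only and 7 Tutored-only, and of the others 312 and 93. Isolate-only examples were chromosome 15 at 5981401 to 5981800 (19 and 40 reads) and chromosome 13 at 3956201 to 3956800 (54 and 40 reads), both with H3K4me3 in all 5 libraries. The 19 reads on chromosome 15 equal the fewest in any island of Isolate replicate 1. Tutored-only examples, chromosome 9 at 17182601 to 17183200 (29 and 40 reads) and chromosome 7 at 13157001 to 13158000 (44 and 40 reads), had H3K4me3 in none. Pol II islands of Isolate reached 65.6% and 49.1% of the H3K4me3 regions in replicates 1 and 2, and those of Tutored 56.9% and 23.4%. Both replicates thus went the same way. The replicates of Tutored lay further apart than the groups did in either replicate, and those of Isolate further apart than the groups did in replicate 1. The Tutored replicate 2 list was the shortest, with 8589 islands against 15198 in Isolate replicate 2. Its islands covered 40.4 Mb against 60.7 Mb, with 49.3 and 53.8 reads per kb.

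With the 8589 densest islands of each library, 388 Pol II regions were Isolate-only and 397 Tutored-only, a balance that equal numbers largely impose. At H3K4me3 regions the counts were then 308 and 105, and elsewhere 80 and 292, where the excess in one place largely forces the deficit in the other. The counts by H3K4me3 were chosen after the data were seen. Of these islands, 73.3% (replicate 1) and 53.8% (replicate 2) lay at H3K4me3 regions in Isolate and 66.3% and 38.5% in Tutored. They are the whole list of Tutored replicate 2 but only the densest part of the other lists. Over full lists the shares were 46.9% and 46.1% in Isolate and 44.1% and 38.5% in Tutored. Taking the densest islands thus raised the share, and part of the gap and of 308 against 105 may come from this trimming. For Pol II the odds ratio of going the same way in both replicates, over all islands, was 2.67 (95% interval 1.94 to 3.66), and 1.76 (1.27 to 2.45) when stratified by the presence of H3K4me3. Neighbouring regions are not independent, so these intervals are too narrow, and 4 libraries can be parted into pairs in only 3 ways, which allows no useful p-value.

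**Figure D2:**
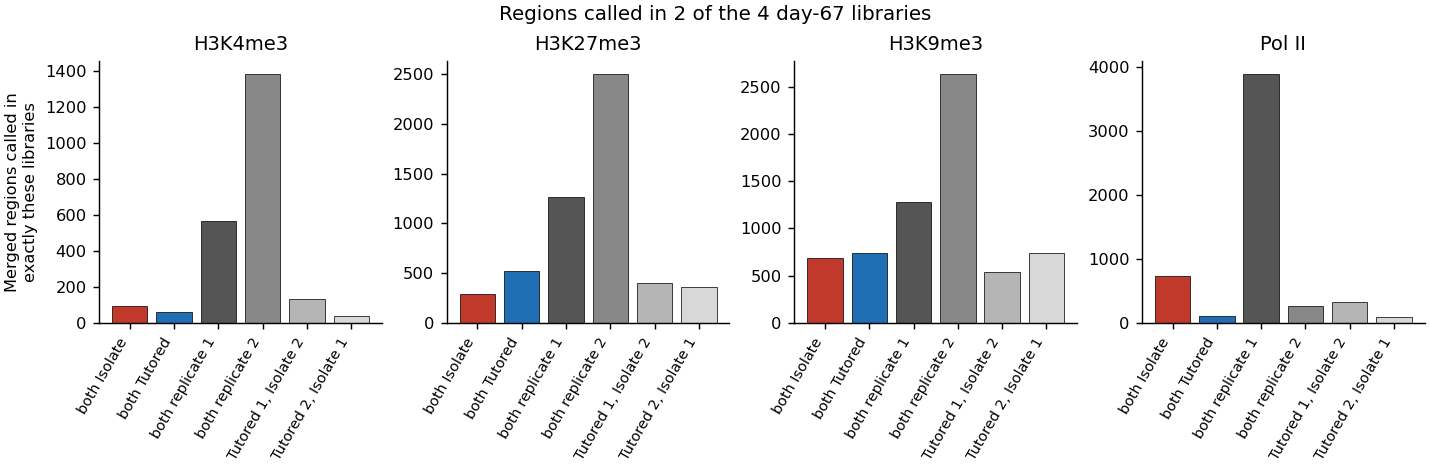
Number of merged regions called in exactly 2 of the 4 P67 libraries, by mark and by which pair of libraries, with both Isolate in red, both Tutored in blue and other pairs in grey. In H3K4me3, 94 and 58 regions separated the groups while 568 and 1385 separated the replicate numbers. In Pol II 735 regions were in both Isolate libraries alone against 100 in both Tutored, and 3905 in both replicate 1 libraries alone against 254 in both replicate 2.

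Read counts inside shared regions gave no region that differed between Isolate and Tutored. edgeR's quasi-likelihood test called 0 regions at a Benjamini-Hochberg adjusted p of 0.05 for each of H3K4me3 (14349 regions tested), H3K27me3 (14211), H3K9me3 (8975) and Pol II (5209). At an unadjusted p under 0.05 there were 9, 99, 129 and 62 regions, and DESeq2 called 0, 0, 0 and 1. Those unadjusted counts are far below what a calibrated test gives without any difference, so the test without a block was conservative. Without Tutored replicate 1 edgeR called 21 Pol II regions, all higher in Isolate, and without Isolate replicate 1 it called 14, of which 3 were higher in Isolate. In these fits the lone library of a group is assumed to vary like the other group. Isolate minus Tutored log2 differences of replicate 1 and replicate 2 correlated across regions at r = -0.03 for H3K4me3, 0.03 for H3K27me3, 0.01 for H3K9me3 and 0.19 for Pol II, although regions are not independent. Differences over 2-fold in both replicates went the same way in 32 Pol II regions and opposite ways in 6, against 37 and 35 in H3K9me3. Simulated data of the same size had 1 common spread for all regions of a mark and no replicate effect. On these the test recovered 71% of 4-fold and 6% of 2-fold changes in H3K4me3 and 60% and 4% in H3K27me3. It recovered 60% and 3% in H3K9me3 and 43% and 0% in Pol II, so few 2-fold changes could be detected without a block. In the real data same-numbered libraries deviated together, so these shares may not hold for them. With the replicate number as a block, edgeR also called 0 regions in each mark (510, 689, 449 and 265 at an unadjusted p under 0.05). On data simulated with a replicate effect and 1 common spread, that fit recovered 99%, 52%, 25% and 31% of 2-fold changes.

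Island sets followed the replicate number more than the group. The mean Jaccard index of covered bases was 0.778 for H3K4me3 libraries of the same replicate number, 0.632 for those of the same group and 0.633 for pairs that shared neither. For H3K27me3 the values were 0.687, 0.589 and 0.589, for H3K9me3 0.477, 0.403 and 0.401, and for Pol II 0.532, 0.399 and 0.385.

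**Figure D3:**
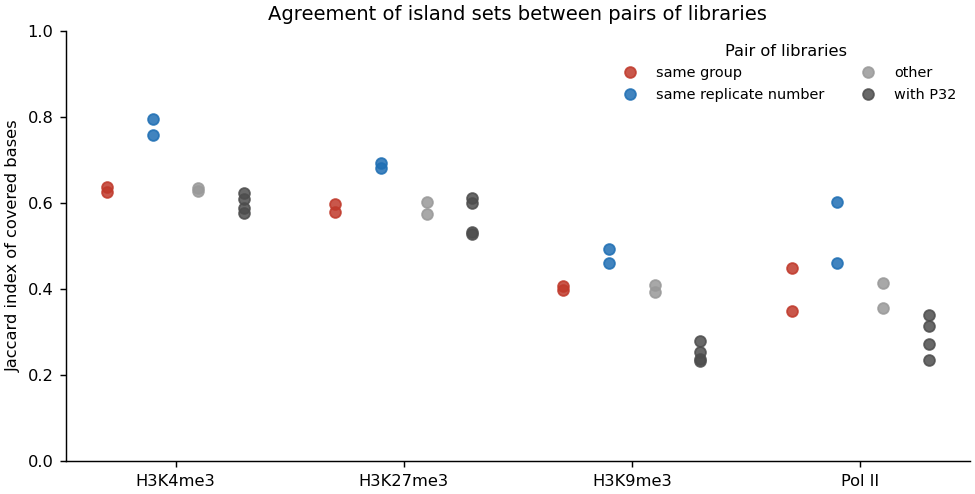
Jaccard index of the bases covered by islands for every pair of libraries of a mark, coloured by whether the pair shares its group, its replicate number, neither, or includes P32. Pairs with the same replicate number averaged 0.778 for H3K4me3 against 0.632 for pairs of the same group, and pairs with P32 were lowest for H3K9me3, at 0.251.

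The second comparison sets P32, juveniles at day 32, against the P67 groups, and asks how chromatin at day 32 differs from that at day 67. In island calls H3K9me3 differed most, with a mean Jaccard index of 0.251 for pairs with P32 and 0.403 for pairs within a P67 group, against 0.290 and 0.399 for Pol II, 0.568 and 0.589 for H3K27me3, and 0.6001 and 0.632 for H3K4me3. Only 27.7% of the 19077 P32 H3K9me3 regions were called in all 4 P67 libraries and 45.9% in none, against 82.95% and 5.39% for H3K4me3, 66.1% and 10.4% for H3K27me3, and 39.6% and 24.6% for Pol II. The marks also differed in agreement without P32. Of merged P67 regions, 28.0% were called in all 4 P67 libraries for H3K9me3, 70.8% for H3K4me3, 46.3% for H3K27me3 and 22.1% for Pol II. Part of the contrast between marks is thus not particular to P32. H3K9me3 covered 16.7% of chromosomes under 20 Mb in P32, and 5.43% to 6.54% in the P67 libraries. It also lay where H3K4me3 was. Of H3K4me3 windows, 29.4% were inside H3K9me3 islands of the same group and replicate number in P32 and 2.71% to 3.90% in P67. P32 H3K4me3 windows were inside H3K27me3 islands in 26.2% of cases, against 14.2% to 15.5% in P67.

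**Figure D4:**
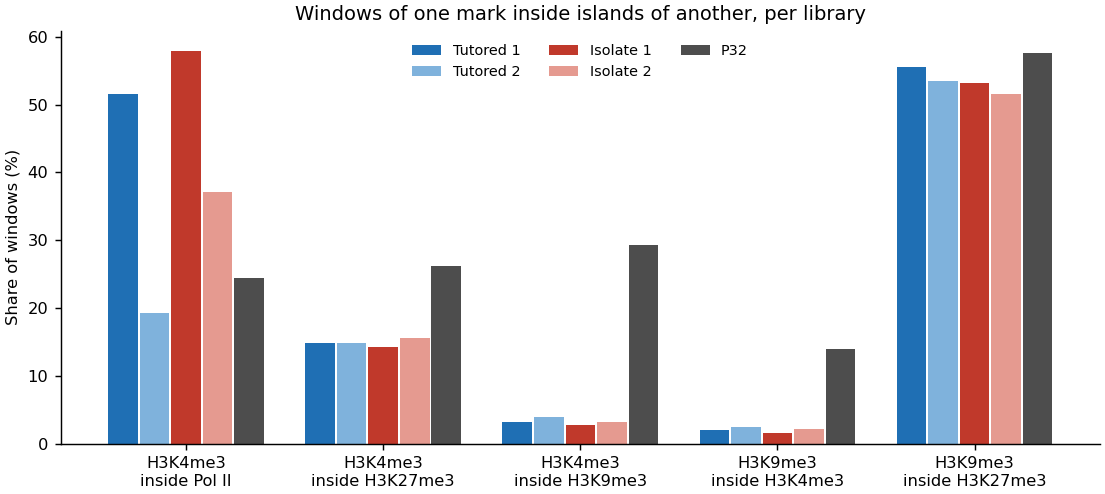
Share of 200 bp windows of one mark (%) that lay inside islands of another mark of the same group and replicate number, with 1 bar per library. P32 (dark grey) stood at 29.4% for H3K4me3 inside H3K9me3, against 2.71% to 3.90% in P67, while H3K9me3 inside H3K27me3 was between 51.6% and 57.5% in the 5 libraries.

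In the count test, 5 H3K9me3 regions passed a Benjamini-Hochberg adjusted p of 0.05 by edgeR, 4 higher and 1 lower in P32. This test takes the single P32 library to vary like the P67 libraries, and the count was unstable, with 0 to 490 regions when 1 P67 library was left out and 554 by DESeq2. The region on chromosome 3 at 31410401 to 31461000, which carried H3K27me3 in all 5 libraries and neither H3K4me3 nor Pol II, fell by 4.55 on the log2 scale (SE 0.35, edgeR adjusted p = 0.0389). It held 848 ± 153 reads in P67 (SD, n = 4) and 36 in P32, with islands over 39.8 ± 4.92 kb and 1.4 kb. On chromosome 11 at 11227601 to 11238200, where all 5 libraries had H3K4me3 and H3K27me3, P32 was higher by a log2 fold of 3.62 (SE 0.36, edgeR adjusted p = 0.0463), with 400 reads against 32.8 ± 7.37. On chromosome 4A at 5804801 to 5826000, with Pol II and H3K27me3 in all 5 libraries, the log2 fold was 3.405 (SE 0.34, edgeR adjusted p = 0.0463), with 619 reads against 33 to 80 in the P67 libraries. The other calls, added here after their values were seen, were chromosome 14 at 8679601 to 8712400 (log2 2.27, SE 0.21), inside the long H3K27me3 region given above, and chromosome 20 at 8268801 to 8293800 (log2 2.60, SE 0.27). In all 5 the difference was mainly one of island length, since reads outside islands were not counted. Without Tutored replicate 1, 0 of the 5286 regions passed by edgeR (1166 at an unadjusted p under 0.05), and edgeR adjusted p-values of the 3 regions named by the rule ranged from 1.29e-08 to 0.0780 over the leave-one-out fits.

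**Figure D5:**
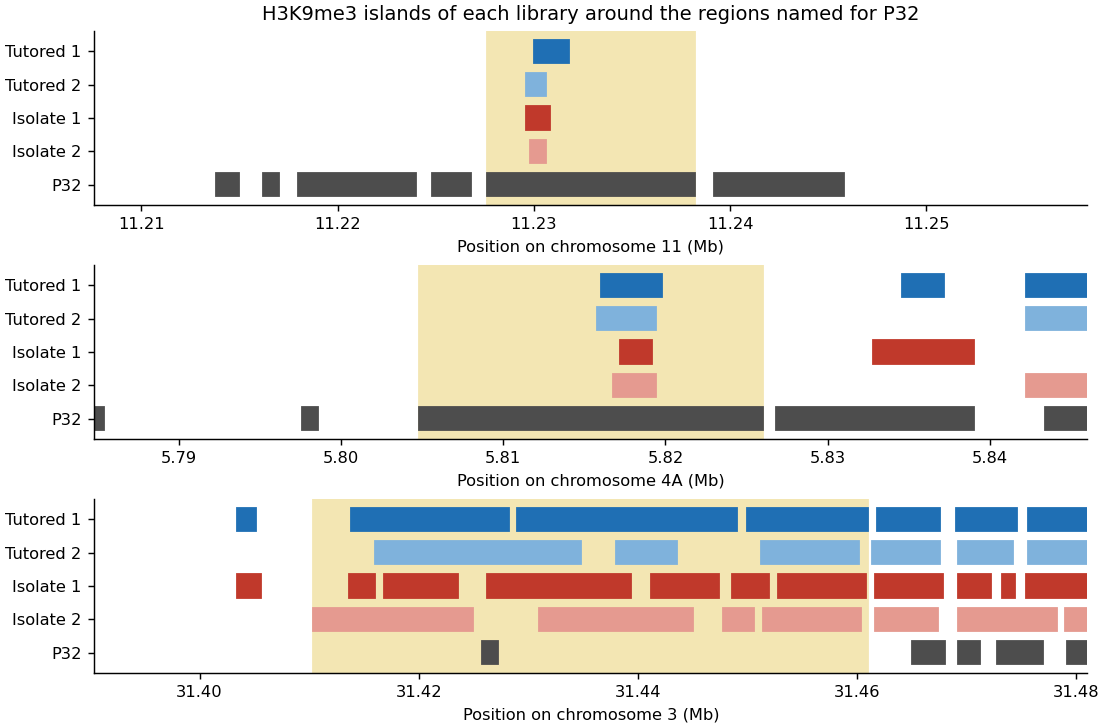
H3K9me3 islands of each library (bars, 1 line per library) along chromosomes 11, 4A and 3 in Mb, with the tested region shaded. P32 islands filled the regions on chromosomes 11 and 4A and covered 1.4 kb of the region on chromosome 3, where P67 islands covered 39.8 kb on average.

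edgeR called 0 regions between P32 and P67 in H3K4me3, H3K27me3 and Pol II, with 3121 of 13513, 1182 of 11659 and 457 of 3651 at an unadjusted p under 0.05. DESeq2 called 1114, 295 and 139 there, and 554 in H3K9me3, so the number of P32 differences depended on the tool. With P32 set against replicate 1 of P67 alone edgeR called 6883 of 13513, 3100 of 11659, 1434 of 5286 and 1107 of 3651 regions in H3K4me3, H3K27me3, H3K9me3 and Pol II, but that fit takes its spread from 2 libraries of the same replicate number alone, which are more alike than replicates. P32 had 1 library per mark, and the labels name no batch. P32 birds also came from the home aviary, unlike both P67 groups. The age of P32 thus cannot be told apart from its housing or from a possible batch of its own.

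Whether P32 resembled Isolate or Tutored was asked of regions called in P32 and in both libraries of 1 P67 group alone. Of these, 61.4% were with Isolate for H3K4me3 (35 against 22, exact binomial 95% interval 47.6 to 74.0), 23.2% for H3K27me3 (44 against 146, 17.4 to 29.8), 35.6% for H3K9me3 (115 against 208, 30.4 to 41.1) and 70.1% for Pol II (68 against 29, 59.96 to 79.0). The intervals cover counting error alone. A share of 50% is not neutral, since Isolate-only and Tutored-only regions differed in number without P32. They numbered 94 and 58 for H3K4me3, 285 and 521 for H3K27me3, 682 and 736 for H3K9me3, and 735 and 100 for Pol II. Against these, Pol II in P32 leaned less to Isolate than its lists, H3K4me3 about as much, and the other marks further to Tutored. With Tutored 1 and Isolate 2 as 1 group, the shares were as far from 50% in H3K4me3 (75.5%), H3K9me3 (32.9%) and Pol II (87.8%). For H3K27me3 that mixed pair gave 47.8%, nearer 50% than the groups, while the split by replicate number gave 22.0% with replicate 1. The side of 50% changed when a single library was left out. That asks for fewer calls in its group and so also moves the base, and these changes need not come from P32. Without Tutored replicate 2 the share was 51.5% for H3K27me3, 53.5% for H3K9me3 and 17.3% for Pol II, and without Isolate replicate 1 it was 37.3% for Pol II. Without Isolate replicate 2 it was 24.7% for H3K4me3, and with equal numbers of islands per library it was 45.7% for H3K4me3 and 23.2% for Pol II.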

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

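The replicate block with equal library sizes, the exchange of H3K4me3 replicate 1 under a block and the restriction to large chromosomes were chosen after seeing the data; the other alternatives were planned. A replicate block called 0 regions between Isolate and Tutored in each mark, with 510, 689, 449 and 265 at an unadjusted p under 0.05 for H3K4me3, H3K27me3, H3K9me3 and Pol II by edgeR, as did the block with equal library sizes (562, 729, 438 and 306) and the exchange under a block (656 in H3K4me3), so the pairing changed no call. The block recovered 99%, 52%, 25% and 31% of simulated 2-fold changes in the 4 marks, with 1 common spread for all regions of a mark. RLE factors, the read minimum, the covered length and regions called in at least 2 libraries, with 0 reads filled in where not called, also gave 0 in each mark, and DESeq2 gave 1 in Pol II. Leave-one-out counts were 0 to 0 in the histone marks and 0 to 21 in Pol II (21 without Tutored replicate 1, 14 without Isolate replicate 1), with the lone library of a group assumed to vary like the other group. The gene lists were not run for lack of an annotation of the build.

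Counts of regions in 1 group stayed within 1.5 times of the reported ones in H3K27me3 and H3K9me3 with 50% cover, equal numbers of islands and islands within 1000 bp merged. H3K4me3 Tutored-only regions moved from 58 to 102 with 50% cover, 98 with equal numbers of islands (against 79 Isolate-only, which turns the order of 94 and 58) and 35 with the replicate 1 groups exchanged. In H3K27me3, Tutored-only regions (417) fell below a mixed pair (448) with equal numbers. Pol II moved to 388 Isolate-only and 397 Tutored-only regions with equal numbers. Leaving out a library asks for fewer calls, so these counts rose by construction: Isolate-only and Tutored-only ranges were 300 to 1064 and 170 to 664 in H3K4me3, 1072 to 2275 and 1417 to 3438 in H3K27me3, 1748 to 4009 and 1848 to 4998 in H3K9me3, and 936 to 4438 and 202 to 2506 in Pol II. Of the 16 regions named for 1 group, 16 kept their side with 50% cover and with equal numbers, and 15 with islands within 1000 bp merged. Equal numbers could hardly change this, since the regions were picked by reads per kb, which also ranks the islands kept. Cover of 50% was likely too, since each region joins islands of its 2 libraries alone and is at most 1.0 kb long. For the 4 in H3K4me3 the exchange of groups ends it by construction.

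The share of P32 regions with Isolate ranged over the leave-one-out settings from 24.7% to 73.2% in H3K4me3, 18.3% to 51.5% in H3K27me3, 20.9% to 53.5% in H3K9me3 and 17.3% to 94.4% in Pol II. In Pol II it was 17.3% without Tutored replicate 2, 37.3% without Isolate replicate 1 and 23.2% with equal numbers of islands, all on the other side of 50% from 70.1%. For Pol II 50% is not neutral, since Isolate-only and Tutored-only regions numbered 735 and 100 without P32. Leaving out a library moved these numbers too, to 936 to 4438 and 202 to 2506, so such shares have another base. In H3K27me3 the share was 51.5% and in H3K9me3 53.5% without Tutored replicate 2. Equal numbers gave 45.7% in H3K4me3 and 44.6% in H3K27me3, 50% cover gave 43.4% in H3K9me3, and the exchange gave 75.5% in H3K4me3. The cause was not tested.

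The P32 count tests moved most. In H3K4me3, H3K27me3, H3K9me3 and Pol II, DESeq2 called 1114, 295, 554 and 139 regions, edgeR against replicate 1 alone (spread from 2 libraries of the same replicate number) 6883, 3100, 1434 and 1107, and leave-one-out fits 697 to 1180, 0 to 0, 0 to 490 and 40 to 273. In H3K9me3 each P67 library moved the count of 5: it was 0 without Tutored replicate 1, 237 without Tutored replicate 2, 339 without Isolate replicate 1 and 490 without Isolate replicate 2. RLE factors gave 107 and the read minimum 116 there. In H3K4me3 the counts were 940, 697, 1180 and 718, and in Pol II 273, 56, 221 and 40, without the same libraries in that order, against 0 with all. The cause was not tested. The log2 fold of the region on chromosome 3 lay between -4.64 and -4.46 over 9 settings (edgeR or DESeq2 adjusted p at most 0.0577), that on chromosome 11 between 3.51 and 3.73 and that on chromosome 4A between 3.24 and 3.62 (at most 0.0780). On chromosomes of at least 50 Mb, P32 H3K9me3 windows inside H3K4me3 islands fell from 13.9% to 11.04%, and H3K4me3 windows inside H3K27me3 islands from 26.2% to 22.8%.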

Other observations

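Chosen after seeing the result were the tests of read numbers and of a rearing difference for Pol II, and the test of the extent of the P32 H3K4me3 islands. Pol II of P32 was spread over the chromosomes unlike that of P67. Its islands covered chromosomes under 20 Mb 1.56 times as densely as large autosomes, against 2.95 to 5.27 times in the P67 libraries. The 254 kb region on chromosome 3 at 22108601 to 22362800, on a large autosome, was covered over 239 kb in P32. That cover is no trait of P32, since 1 library of each P67 group covered it about as widely. P67 cover was 142 ± 145 kb in Tutored and 135 ± 150 kb in Isolate (SD, n = 2 each). Across chromosome sizes H3K27me3 of P32 went the other way from Pol II. It covered 25.2% of chromosomes under 20 Mb in P32 and 21.03% to 22.6% in P67, a ratio to large autosomes of 3.72 against 1.85 to 2.67. H3K4me3 regions with H3K9me3 in all 4 P67 libraries numbered 324 and held a median of 8.58 H3K4me3 CPM per kb, against 16.3 over all H3K4me3 regions. No explanation was tested for these values.

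Pol II regions called in both Isolate libraries alone outnumbered those in both Tutored libraries alone by 7.35 to 1. With equal numbers of islands the ratio was 0.977, but equal numbers pull such counts together by construction (0.789 to 0.979 in the other marks), so the shorter list of Tutored replicate 2 stays open as a source. Unequal numbers of reads used to call islands in replicate 2 are argued against by scaling factors in the ratio 1.00, while the depth before reads were brought to a common number, if they were, is unknown. Chromosome-wide shifts as the whole source of same-way calls are argued against by an odds ratio of 2.76 (95% interval 1.99 to 3.81) when stratified by chromosome. A rearing difference shared by both replicates cannot be told apart from a difference in enrichment between libraries, since each group has 2 libraries. The odds ratio was at or above 2.55 under 4 choices of islands. It was 2.44 (95% interval 0.969 to 6.12) at H3K4me3 regions and 1.70 (1.19 to 2.41) away from them. Stratified by H3K4me3 and chromosome it was 1.68 (1.19 to 2.38).

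P32 H3K9me3 windows lay inside H3K4me3 islands in 13.9% of cases, against 1.56% to 2.51% in P67. The chromosome-size trend of the P32 library is not the whole cause, since the share was 11.04% on chromosomes of at least 50 Mb (P67 at most 2.04%), nor is the extent of its H3K4me3 islands, since 8.80% lay inside windows shared by the 4 P67 H3K4me3 libraries (P67 at most 1.77%). For carry-over of H3K4me3-marked chromatin into the P32 H3K9me3 library, the share of H3K4me3 regions with an H3K9me3 island was 0.873 times as high in the quartile with most H3K4me3 reads per kb as in the quartile with fewest. That bound, set at 1, overlooked that this ratio is 0.113 to 0.170 in P67, and the rise over the P67 mean was 29.1 percentage points in the top quartile and 25.4 in the bottom one, so carry-over stays open. Age, housing, batch and base composition, for which no genome was used here, also stay open.

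P32 H3K4me3 windows lay inside H3K27me3 islands in 26.2% of cases, against 14.2% to 15.5% in P67. A chromosome-size trend is not the whole cause, since the share was 22.8% on chromosomes of at least 50 Mb (P67 at most 14.6%). Shorter P32 H3K4me3 islands are not either, since 21.2% of the windows shared by the 4 P67 H3K4me3 libraries lay inside P32 H3K27me3 islands (P67 at most 15.1%). A higher overlap of the marks in younger birds is a possible explanation that was not tested. P32 is 1 library per mark, differs from P67 in housing and may have a batch of its own.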
